A study of Mus musculus with 4 samples.

How the data were processed

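RNA was measured by poly(A) selection and sequencing in 4 libraries of transformed mouse lineage-negative bone marrow cells, 2 of cells with the MLL-ENL fusion and 2 of cells with the fusion that lacks the YEATS domain. Per the labels' protocols RNA was prepared with a Qiagen RNeasy kit, mRNA was selected with a Lexogen kit and libraries were made with a Swift RNA kit. The submitters' processing notes name cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3 and the mouse build GRCm38. Their settings, the annotation release, the strand setting and the way reads of the introduced fusion were counted are not given in the sources used here. Overlapping and antisense genes and near-identical copies are therefore uncertain where reads could be split between them.

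The authors deposited a table of expected counts per gene, which are RSEM estimates of the reads from each gene and were whole numbers as deposited, and a table of FPKM, which the authors scaled by gene length and library size. Both tables hold 55426 genes, of which 33627 were at 0 in all 4 libraries. Totals were 28121268, 27812855, 28814798 and 28177480 expected counts. At these depths 3 counts correspond to 0.112, 0.107, 0.102 and 0.105 CPM, which was used as the floor for genes with no counts in a group. Floors and intervals cover counting error only, since reads were not marked by molecular identifiers. Dates stood in place of 27 symbols, and these genes were named from their Ensembl identifiers with GENCODE mouse release M21, which matched 55240 identifiers and also gave positions and exonic lengths.

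Groups were taken from the titles of the samples. The expected counts were used as whole numbers. Genes were filtered with edgeR's filterByExpr, which left 13245, and libraries were scaled by TMM factors (0.953, 1.012, 1.02 and 1.018). Differences were tested with edgeR's quasi-likelihood F-test (glmQLFit with legacy set to true, glmQLFTest; edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. SE of a log2 fold change was its size divided by the square root of F. Counts with a log2 fold change of at least 1 in size were also taken. With 2 residual degrees of freedom and a prior of 3.41, all tests rest on the spread within 2 pairs of libraries. A chi-square comparison of counts found more than sampling noise in both pairs. Each library was counted as a replicate, although such noise does not make libraries of a line independent replicates of a genotype.

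Before the data were examined, 30 gene lists were fixed, of which 27 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with fry and with camera at an estimated correlation. Of the 27 lists 11 were called with the preset correlation, 0 with an estimated correlation (2 at an unadjusted p under 0.05, immediate-early and cholesterol synthesis genes) and 11 by fry (7 of these shared with the preset correlation), which tests whether a list's genes move on balance one way and does not compare them with other genes. Over all lists 1 member had no matching symbol. The lists overlap in part: Kit, Meis1 and Sox4, for example, stand in more than 1.

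Genes named in the text were chosen by a rule fixed before the data were examined. It takes a fixed set that includes Mllt1, Kmt2a, Hoxa9, Hoxa10, Meis1, Eya1, Mecom, Myc, Bcl2, Xist and Ddx3y, the 12 largest increases and 12 largest decreases among called genes with separated libraries and a mean of at least 10 CPM in the higher group, without predicted genes, clone names and immunoglobulin or T-cell receptor segments, and per tested list the 2 called members with the largest change in each direction at a mean of 1 CPM or more in the higher group, or, with none, the 2 with the smallest p. Not every gene that the rule takes is printed. Genes outside this rule were chosen after their values were seen, and the text says so where it names them.

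On simulated counts made from the means and depths of these libraries, with 200 of 13245 genes changed and an equal spread in both groups, the test recovered 10.7%, 63.9% and 91.8% of genes changed 1.5-, 2- and 4-fold, with 12.2 false calls per run. With each group given the spread of its own pair, as 1 value for all genes, it recovered 1.49%, 17.9% and 76.7%, with 0 false calls. Fewer genes were changed than were called in the data, which makes the adjusted threshold stricter, so these shares do not give the sensitivity on the data.

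Alternatives fixed before the data were examined were other scalings, no filter and a stricter filter, a replicate block, each library left out, limma on log2 FPKM with pseudocounts of 1 and 0.1, DESeq2 1.42.0, limma-voom, a robust fit, glmTreat and the removal of mitochondrial, ribosomal-protein and haemoglobin genes. Removal of a gene-length trend (a lowess with span 0.3 on log exonic length) and voom with library quality weights were added after the data were seen. Further tests used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib.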

Results

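Poly(A)-selected RNA was sequenced from mouse haematopoietic stem and progenitor cells that had been transformed by an MLL-ENL fusion. In such a fusion the N-terminal part of the histone methyltransferase MLL (Kmt2a) is joined to sequence of ENL (Mllt1), a chromatin reader of the super elongation complex. Cells with the MLL-ENL fusion were set against cells with a fusion that lacks the YEATS domain of ENL, the module that binds acylated lysines on histone tails (called MLL-ENL dYEATS here). The label of the mutant gives ENL residues 372 to 559, so all ENL sequence before residue 372 is absent from it. The ENL residues of the MLL-ENL fusion are not given in the sources used here, and differences cannot be assigned to the YEATS domain alone. The 4 libraries fall into 2 groups of 2, and the series' design text calls the libraries of a group technical replicates. Total expected counts were 28121268 and 27812855 in the MLL-ENL libraries and 28814798 and 28177480 in the MLL-ENL dYEATS libraries. Values are counts scaled to a common library size (CPM) with SD over n = 2 libraries, and log2 fold changes are MLL-ENL dYEATS minus MLL-ENL with their standard errors (SE). How many lines were made per genotype is not given in the sources used here. From the words technical replicates, the libraries of a group are taken to come from 1 line, in which case adjusted p-values measure the spread between libraries of a line, and genotype and line cannot be separated.

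Transcripts of both fusion partners were measured first. Mllt1 (chromosome 17, 56892611 to 56935415, GRCm38) lay at 67.7 and 62.1 CPM in the MLL-ENL libraries and at 64.0 and 59.3 CPM in the MLL-ENL dYEATS libraries. Kmt2a (chromosome 9, 44803355 to 44881296) lay at 51.9 and 84.1 CPM against 70.5 and 67.9 CPM. Neither passed the test with all 4 libraries (adjusted p = 0.692 and 0.952). Kmt2a was called lower without MLL-ENL replicate 1 (log2 fold change -0.28) and higher without MLL-ENL replicate 2 (0.42). Mllt1 was called lower without MLL-ENL replicate 2 (-0.14). These reads count the mouse genes as annotated, and how reads of the introduced fusion were counted is not given in the sources used here, so they do not check which fusion a library carried. The MLL-ENL pair was further apart than the MLL-ENL dYEATS pair. Chi-square per degree of freedom was 89.8 against 1.99 over genes with at least 10 counts. Between the groups it was 137 for the libraries numbered 1 and 79 for those numbered 2. By this measure alone MLL-ENL replicate 2 was as far from MLL-ENL replicate 1 as from the mutant. It weighs genes with many counts most and included the ribosomal RNA gene named below. The median chi-square over genes, relative to sampling noise, was 14.1 in the MLL-ENL pair and 15.7 between the libraries numbered 2. The SD of the log2 ratio was 0.474 in the MLL-ENL pair, against 1.082 and 1.033 between the groups. The correlation of log2 CPM was higher in the MLL-ENL pair (0.9864) than between the groups (0.9317 and 0.9378). In the MLL-ENL pair the log2 ratio of replicate 1 to replicate 2 fell with exonic length across 13237 genes (Spearman's rho = -0.393), which are not independent replicates. CT010467.1, a gene annotated as ribosomal RNA and chosen after its values were seen, took 9.25% of the counts in MLL-ENL replicate 1 and 4.94%, 5.46% and 5.42% in MLL-ENL replicate 2 and MLL-ENL dYEATS replicates 1 and 2.

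**Figure D1:**
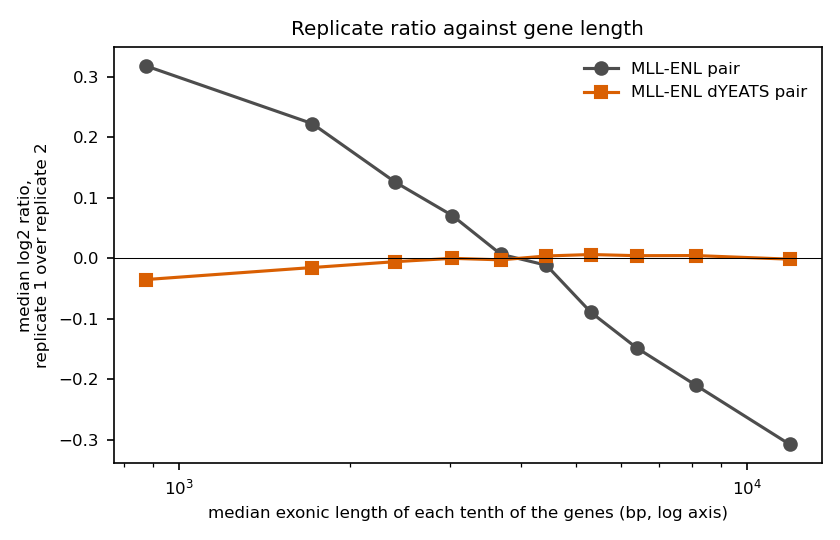
Median log2 ratio of replicate 1 over replicate 2 (vertical axis) for 10 bins of genes ordered by exonic length in bp (log horizontal axis), for the MLL-ENL pair (circles) and the MLL-ENL dYEATS pair (squares). In the MLL-ENL pair the median went from 0.32 in the shortest bin to -0.31 in the longest, and in the MLL-ENL dYEATS pair the medians of these bins were -0.04 and -0.0014.

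The comparison addressed which transcripts differ between cells with the MLL-ENL fusion and cells with the shortened fusion. Of 13245 genes tested, 932 were higher and 1303 lower in the MLL-ENL dYEATS libraries (edgeR's quasi-likelihood test, adjusted p under 0.05), and 555 and 851 of these differed by at least 2-fold. Several genes with reads in the MLL-ENL libraries had no counts at all in the MLL-ENL dYEATS libraries. Eya1, a phosphatase and transcriptional co-activator (chromosome 1, 14168954 to 14310235), was at 37.4 ± 1.46 CPM in the MLL-ENL libraries and at 0 in both MLL-ENL dYEATS libraries, at least 358-fold lower against a floor of 3 counts per library. By the same floor Cntln, a centriolar protein, was at least 429-fold lower, Csn2 (beta-casein) at least 159-fold, Xlr4b at least 150-fold and the galactosyltransferase B3galt1 at least 119-fold. Nmral1, with 2 counts in the MLL-ENL dYEATS libraries, had a ratio of 1078 (95% interval of counting error 298 to 8907), Xlr3b one of 615 (210 to 2987), and Rasgrf2, a guanine nucleotide exchange factor for Ras, one of 700 (125 to 27674). Rai14 and Stra6, with 2 and 3 counts in the MLL-ENL dYEATS libraries, had ratios of 368 (102 to 3047) and 277 (94.5 to 1347). Kctd17 and Gcnt4, which complete the 12 largest decreases, fell from 31.1 to 0.0864 CPM and from 26.3 to 0.155 CPM. Xlr3b and Xlr4b belong to a family of near-identical copies, so their split of reads is uncertain.

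Among increases, Psma8, a testis-type proteasome subunit, went from 0 to 20.5 ± 0.574 CPM, at least 183-fold higher, and Gpx3, a secreted glutathione peroxidase, had a ratio of 883 (244 to 7295) on 2 counts in the MLL-ENL libraries. Plp2, an X-linked membrane protein, rose from 0.421 ± 0.143 to 105 ± 2.22 CPM (adjusted p = 0.000188). Abcc8, a subunit of potassium channels, rose from 0.273 to 34.5 CPM, the actin-binding Tpm4 from 1.20 to 81.0 CPM, the proenkephalin gene Penk from 3.17 to 97.6 CPM and Lmna, which encodes the A-type lamins, from 3.27 to 63.8 CPM. Endod1, Crybg1, Adam8, Pcdh7 and Sh3pxd2a complete the 12 largest increases, with log2 fold changes of 5.87, 5.17, 4.77, 4.39 and 4.30, and Endod1 had 6.49 without MLL-ENL replicate 1. In every called gene both libraries of one group lay on one side of both libraries of the other. Chance gives this in 33.3% of genes for 2 against 2. The calls rest on the same values, so the separation is no further support for them. Without MLL-ENL replicate 1 or 2 the spread rested on the close MLL-ENL dYEATS pair, and 7465 and 9099 genes were called. Without MLL-ENL dYEATS replicate 1 or 2 the numbers were 1419 and 1392. With limma on log2 FPKM it was between 674 and 1135, and with a minimum of 5 CPM in 2 libraries 1350.

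**Figure D2:**
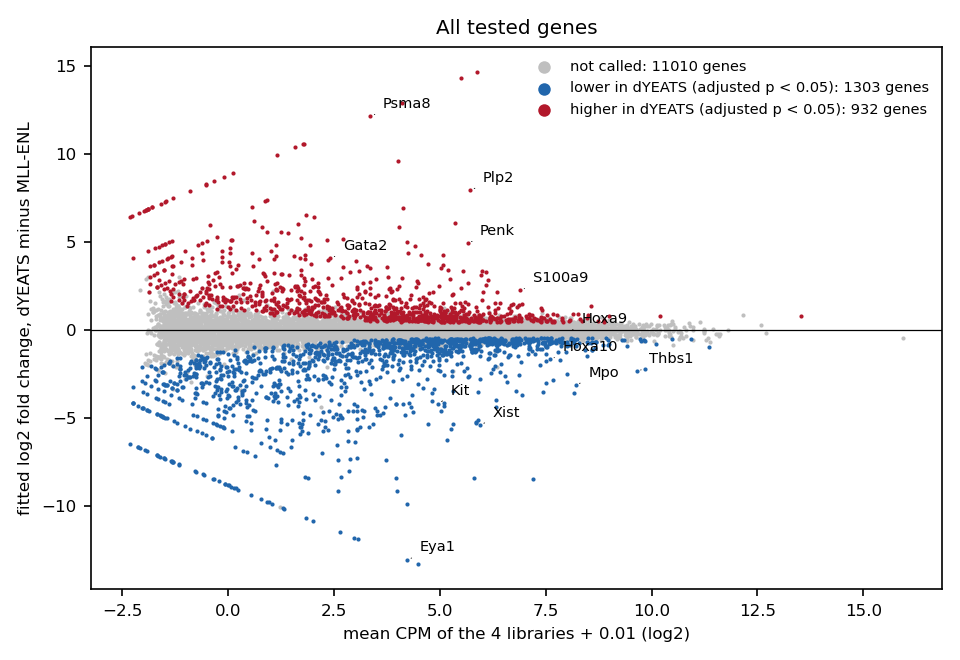
Fitted log2 fold change (MLL-ENL dYEATS minus MLL-ENL, vertical axis) against the log2 of mean CPM plus 0.01 (horizontal axis), 1 point per tested gene, red for the 932 called higher, blue for the 1303 called lower and grey for the rest. Points on the slanted lines are genes with no counts in one of the groups, such as Eya1 and Psma8, whose fitted values depend on the prior count and are no measured folds.

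Homeobox genes of the HoxA cluster, the best known targets of MLL fusions, did not move as a block. Hoxa9 lay at 268 ± 1.02 CPM in the MLL-ENL libraries and at 259 ± 5.18 CPM in the MLL-ENL dYEATS libraries (adjusted p = 0.766). Hoxa10 (chromosome 6, 52231197 to 52240854), next to it, fell from 294 ± 10.5 to 94.8 ± 0.445 CPM (log2 fold change -1.63 ± 0.10 SE, adjusted p = 0.000771), Hoxa11 fell by 1.17 on the log2 scale, and Hoxa5 rose from 20.7 ± 2.29 to 61.2 ± 0.928 CPM (adjusted p = 0.00163). Of 10 tested HoxA genes 1 rose and 2 fell (2 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.988). Its median was 0.10 and its mean 0.0013, both above 0, where the set test pointed down.

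Of 24 other known targets of MLL fusions 6 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0431, and adjusted p = 0.856 with an estimated correlation), and 17 were not called. The median was -0.07, and it was -0.26 without MLL-ENL replicate 1 and 0.02 without MLL-ENL replicate 2. The mean of -1.01 (-0.82 with Eya1 at its bound) rests on a few members. Besides Eya1, the adhesion receptor Adgra3 fell from 33.4 to 0.534 CPM, the transcription factor Sox4 from 15.6 ± 1.90 to 0.773 ± 0.304 CPM and Runx1, a regulator of blood cell formation chosen after its values were seen, from 111 to 52.7 CPM. Meis1, the Hox cofactor, fell from 94.9 ± 0.858 to 56.0 ± 3.23 CPM (adjusted p = 0.00997). Mef2c, also chosen after its values were seen, fell by 0.65 on the log2 scale and was not called without MLL-ENL dYEATS replicate 1 or 2 (adjusted p = 0.311 and 0.221), with scaling by library totals (0.0516) or with limma on log2 FPKM (0.271, 0.274 and 0.423). Lmo2 rose from 217 to 315 CPM. Myc was at 222 ± 80.5 and 239 ± 1.93 CPM (adjusted p = 0.805) and Bcl2 at 12.1 and 15.2 CPM (0.136), and Mecom had 1 count in all. The calls of Meis1 (adjusted p = 0.122 and 0.239) and Lmo2 (0.442 and 0.475) ended without MLL-ENL dYEATS replicate 1 or 2. The list was not called in 6 of 14 alternatives: without a filter (adjusted p = 0.1), with limma on log2 FPKM (0.14, 0.14 and 0.2), once the gene-length trend was removed (0.154) and without MLL-ENL replicate 2 (0.711). Myc was called lower without MLL-ENL replicate 1 (log2 fold change -0.23) and higher without MLL-ENL replicate 2 (0.53). Bcl2 was called higher without MLL-ENL replicate 1 (0.37) and without MLL-ENL replicate 2 (0.27).

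Members of the super elongation, DOT1L and PAF1 complexes, through which ENL acts on transcription, moved little. Eaf1 rose from 115 to 185 CPM and Mllt6 fell from 18.7 to 9.87 CPM, the 1 higher and 1 lower of 23 tested members (1 and 1 adjusted over the list alone; list adjusted p = 0.805). The call of Eaf1 ended without MLL-ENL dYEATS replicate 1 or 2 (adjusted p = 0.219 and 0.248; log2 fold change 0.69 and 0.67) and with limma on log2 FPKM (0.0739, 0.079 and 0.162). That of Mllt6 ended without MLL-ENL dYEATS replicate 2 (0.106; log2 fold change -0.81) and with limma on log2 FPKM (0.0884, 0.0994 and 0.187).

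**Figure D3:**
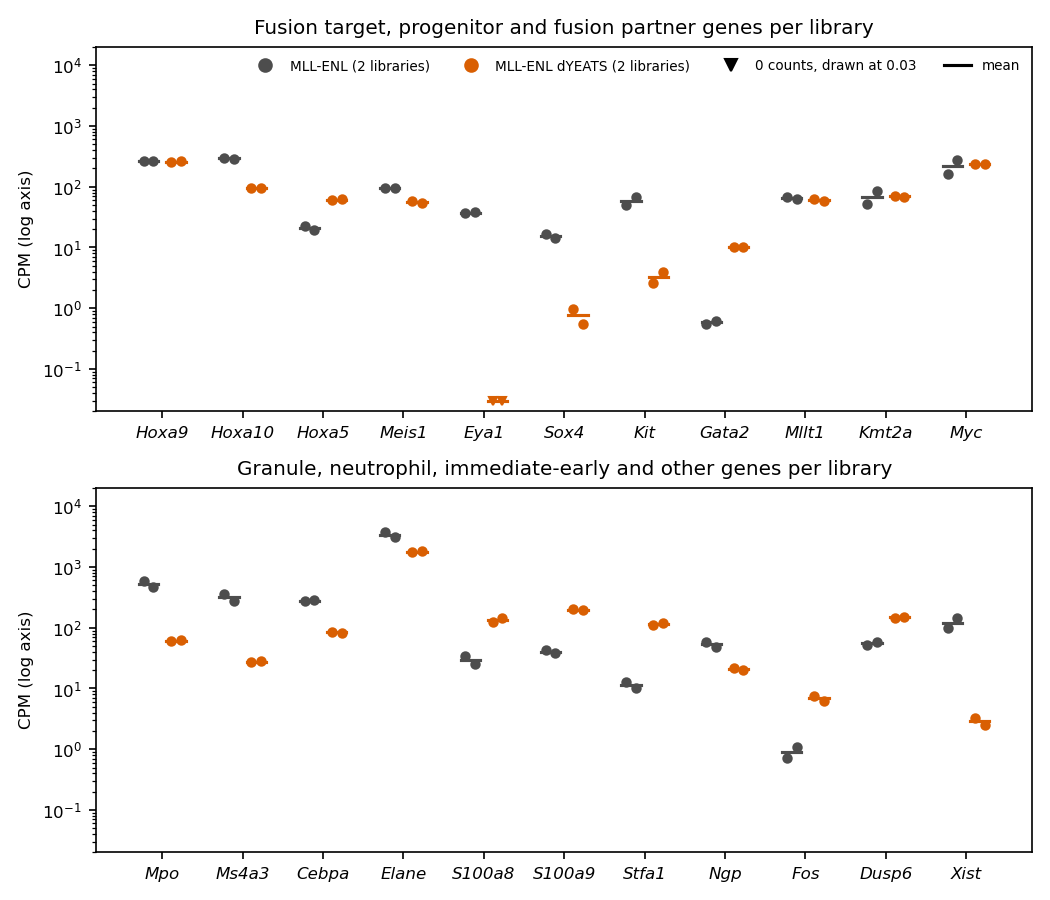
CPM (log vertical axis) of selected genes in each library, grey for MLL-ENL and orange for MLL-ENL dYEATS, with bars at the mean of 2 libraries and triangles at 0.03 for 0 counts. Hoxa9 lay at 268 and 259 CPM, whereas Hoxa10, Eya1, Sox4, Kit, Mpo and Xist were lower and Hoxa5, Gata2, S100a9 and Fos higher in both MLL-ENL dYEATS libraries.

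Primary granule genes were lower, and part of the later neutrophil genes were higher. Of 14 primary granule genes, made in promyelocytes, 7 fell and 0 rose (7 and 1 adjusted over the list alone; camera adjusted p = 3.93e-05, and adjusted p = 0.638 with an estimated correlation). Ms4a3 fell from 317 ± 64.8 to 27.6 ± 0.401 CPM and Nkg7, the largest decrease of the list on the log2 scale, from 3.98 to 0.329 CPM. Among members chosen after their values were seen, myeloperoxidase (Mpo) fell from 530 ± 90.9 to 60.9 ± 2.07 CPM (adjusted p = 0.000429) and the granulocyte transcription factor Cebpa from 279 ± 3.10 to 84.3 ± 2.53 CPM. Neutrophil elastase (Elane) fell by 0.93 on the log2 scale, a call that ended without MLL-ENL dYEATS replicate 1 or 2 (adjusted p = 0.12 and 0.0964). Of 26 later neutrophil genes 11 rose and 3 fell (12 and 5 adjusted over the list alone; adjusted p = 0.000485, and adjusted p = 0.656 with an estimated correlation), and 12 were not called. Stfa1, which has near-identical copies, rose from 11.3 to 116 CPM and the matrix protease Mmp9 from 0.871 to 5.07 CPM. The calprotectin subunits S100a8 and S100a9, chosen after their values were seen, had log2 fold changes of 2.16 and 2.29, with S100a9 going from 40.4 ± 3.33 to 198 ± 2.85 CPM. Chil3 and Lcn2, chosen in the same way, rose from 15.5 to 62.1 CPM and from 12.3 to 36.2 CPM. The 3 that fell were Ngp (54.0 to 20.9 CPM; chosen after its values were seen), Cd177 (90.2 to 32.7 CPM) and Lrg1 (12.4 to 1.33 CPM). The later neutrophil list was not called with limma on filtered log2 FPKM, with adjusted p from 1.08e-05 to 0.133 over 14 alternatives.

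Of 20 monocyte and macrophage genes 6 rose and 2 fell (8 and 4 adjusted over the list alone; adjusted p = 0.205). Ms4a6c rose from 0.983 to 5.96 CPM, Mpeg1, which forms pores in phagosomes, from 12.1 to 29.7 CPM, whereas Gpnmb and Ly6c2 fell by 0.90 and 0.64 on the log2 scale. The call of Ly6c2 ended without MLL-ENL dYEATS replicate 1 or 2 (adjusted p = 0.422 and 0.324), and that of Gpnmb without replicate 2 (0.0799).

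Haematopoietic stem and progenitor genes were lower as a list, with 7 of 13 tested members lower and 2 higher (7 and 3 adjusted over the list alone; adjusted p = 0.0381, and adjusted p = 0.656 with an estimated correlation). Kit, the receptor of stem cell factor, fell from 58.7 ± 11.7 to 3.27 ± 0.909 CPM (log2 fold change -4.17 ± 0.26 SE, adjusted p = 0.000681), and Sox4 also counts here. Gata2, a transcription factor of early progenitors and mast cells, rose from 0.582 ± 0.0314 to 10.1 ± 0.0753 CPM (adjusted p = 0.000387). The other member called higher, Gata3, was chosen after its values were seen and had few counts (log2 fold change 2.67, 2.05 without MLL-ENL replicate 1 and 3.86 without MLL-ENL replicate 2). Gata3 was not called with DESeq2 (adjusted p = 0.0683), with library quality weights (0.0997) or with limma on unfiltered log2 FPKM (0.421). The list was not called without a filter (adjusted p = 0.372), with a minimum of 5 CPM (0.0617), with limma on unfiltered log2 FPKM (0.2) and once the gene-length trend was removed (0.111).

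Markers of cell types other than granulocytes and monocytes were mostly under the detection filter. Of 7 tested dendritic cell and MHC class II genes 1 rose and 2 fell (1 and 4 adjusted over the list alone; adjusted p = 0.44). The integrin Itgax, with 3 counts in the MLL-ENL libraries, rose with a ratio of 37.5 (12.5 to 185). H2-Ab1, with 2 counts in the MLL-ENL dYEATS libraries, had a ratio of 114 (31.1 to 944), and H2-DMb1 fell by 0.65 on the log2 scale, a call that ended in 9 alternatives (adjusted p from 0.0514 with a robust fit to 0.301 without MLL-ENL dYEATS replicate 2). Of 7 megakaryocyte genes 1 rose (Cd9) and 0 fell (0 and 0 adjusted over the list alone; adjusted p = 0.781). Of 7 mast cell, basophil and eosinophil genes 2 rose and 1 fell (2 and 2 adjusted over the list alone; adjusted p = 0.743): Gata2 and Ear2 (the latter chosen after its values were seen, with 2 counts in the MLL-ENL libraries and a ratio of 25.5, 6.74 to 216) rose, and the histidine decarboxylase gene Hdc fell from 8.56 to 2.81 CPM. Of 6 T-lymphoid and NK genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.171), and Thy1, with 4 and 0 counts in MLL-ENL dYEATS replicates 1 and 2, had a ratio of 52.8 (20.3 to 196). Of 8 stromal and endothelial genes 2 rose and 3 fell (2 and 4 adjusted over the list alone; adjusted p = 0.727, and 0.00581 without MLL-ENL replicate 1). Pecam1 rose from 5.20 to 60.2 CPM, where thrombospondin 1 (Thbs1) fell from 1343 ± 527 to 265 ± 2.33 CPM. Median, mean and test differed in sign for megakaryocyte (-0.37, -0.02, up), mast cell (-0.46, 0.77, up) and stromal genes (-0.26, 0.06, down). The call of Cd9 ended without MLL-ENL dYEATS replicate 1 or 2 (adjusted p = 0.351 and 0.171), with DESeq2 (0.108), with library quality weights (0.193) and with limma on log2 FPKM (0.068, 0.083 and 0.158). Erythroid and B-lymphoid lists had 4 and 2 tested members, too few for the test, and 0 and 0 of these rose and 1 and 1 fell.

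Immediate-early genes, which respond within minutes to growth factor signalling, were higher as a list, with 10 of 23 tested members higher and 0 lower (13 and 1 adjusted over the list alone; adjusted p = 1.24e-07, and adjusted p = 0.456 with an estimated correlation). The AP-1 genes Fos and Fosl1 rose from 0.906 ± 0.278 to 6.97 ± 0.977 CPM and from 0.672 to 5.95 CPM. Among members chosen after their values were seen, Nr4a1 rose from 0.911 to 5.08 CPM, Klf2 from 3.29 to 15.4 CPM and the ERK phosphatases Dusp5 and Dusp6 from 2.52 ± 0.499 to 14.0 ± 0.094 CPM and from 55.8 ± 4.15 to 149 ± 5.62 CPM (adjusted p = 0.00126 and 0.00163). Of 21 genes of NF-kB signalling and inflammatory cytokines 4 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.114). Tnfaip3 and Ccl6 had log2 fold changes of 1.68 and 1.38 and Nlrp3 and Icam1 of -1.86 and -0.87, the last not called without MLL-ENL dYEATS replicate 1 or 2 (adjusted p = 0.074 and 0.0568). Nlrp3 was not called with limma on log2 FPKM (adjusted p = 0.0681, 0.0804 and 0.116).

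Interferon-stimulated genes were lower, with 9 of 22 tested members lower and 1 higher (10 and 2 adjusted over the list alone; adjusted p = 0.0035, and adjusted p = 0.594 with an estimated correlation). The RNA sensor Oas1a, which has near-identical copies, fell from 22.0 ± 3.98 to 0.916 ± 0.235 CPM, the nucleic acid sensor Zbp1 from 2.78 to 0.466 CPM and the immunoproteasome subunit Psmb8, chosen after its values were seen, from 70.9 to 19.2 CPM. Oas3 rose from 0.292 to 1.19 CPM, a call that ended without MLL-ENL dYEATS replicate 2 (adjusted p = 0.119) and with library quality weights (0.187), and the list was not called with limma on log2 FPKM without a filter (0.0796; 0.00279 to 0.0796 over 14 alternatives).

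Receptors changed in both directions. Of 23 cytokine receptor genes 3 rose and 3 fell (6 and 5 adjusted over the list alone; adjusted p = 0.745). Besides Kit, Il2ra fell by 3.94 on the log2 scale. Csf1r, the receptor of a macrophage growth factor, rose from 4.73 to 9.22 CPM, a call that ended without MLL-ENL dYEATS replicate 1 (adjusted p = 0.102). Il6ra had a log2 fold change of 0.61 and was not called without MLL-ENL dYEATS replicate 1 or 2 (adjusted p = 0.342 and 0.259). Of 26 adhesion and homing receptors 7 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.0266, and adjusted p = 0.8 with an estimated correlation). The chemokine receptor Ccr1 rose from 5.17 ± 1.19 to 26.3 ± 1.23 CPM and Cd44, chosen after its values were seen, from 107 to 233 CPM. The adhesion list was not called in 6 of 14 alternatives: with a minimum of 5 CPM (adjusted p = 0.32), with limma on log2 FPKM (0.237, 0.236 and 0.0796), once the gene-length trend was removed (0.0679) and without MLL-ENL replicate 1 (0.514).

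**Figure D4:**
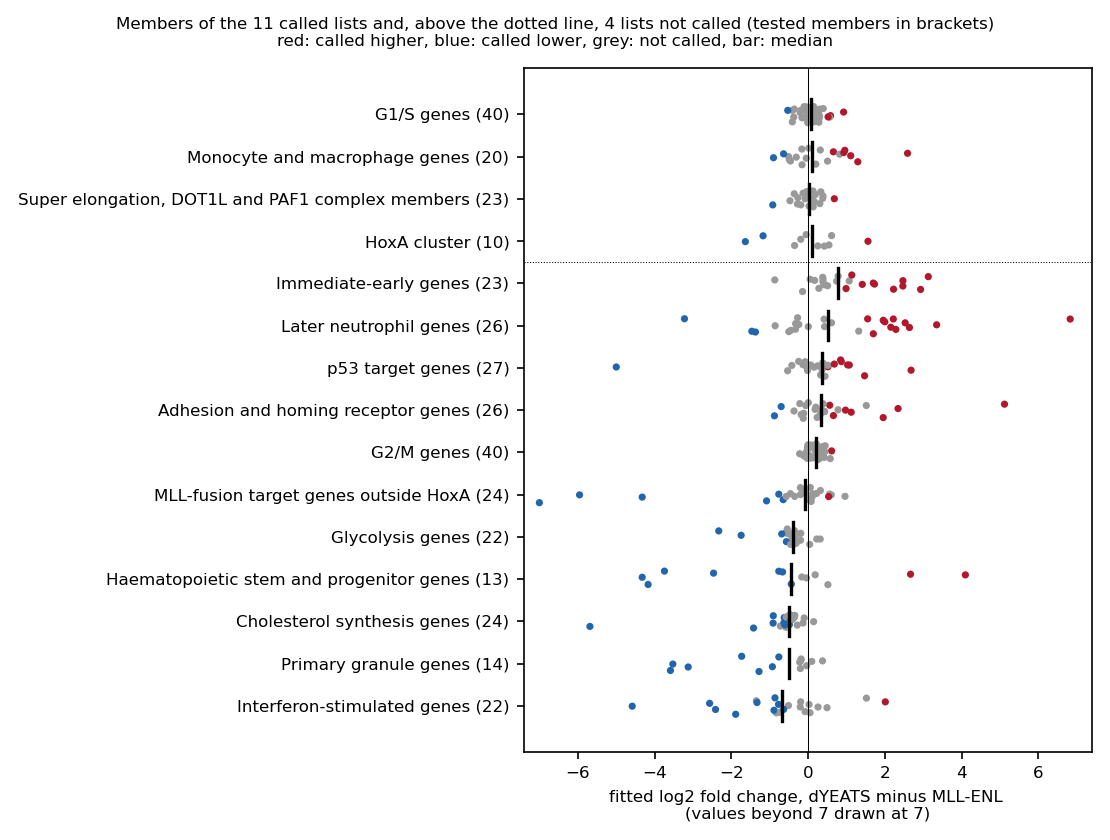
Fitted log2 fold changes (horizontal axis, MLL-ENL dYEATS minus MLL-ENL) of the tested members of 11 called lists and of 4 lists that were not called, 1 point per gene, with a bar at each list's median and values beyond 7 in size drawn at that limit. Medians of the called lists ran from -0.68 for interferon-stimulated genes to 0.79 for immediate-early genes.

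Of 24 cholesterol synthesis genes 11 fell and 0 rose (17 and 0 adjusted over the list alone; adjusted p = 2.38e-05, and adjusted p = 0.456 with an estimated correlation), and 13 were not called. The sterol reductase gene Tm7sf2 fell from 44.3 to 16.5 CPM. Of 22 glycolysis genes 5 fell and 0 rose (6 and 0 adjusted over the list alone; adjusted p = 0.00267, and adjusted p = 0.656 with an estimated correlation), and 17 were not called. The aldolase gene Aldoc fell from 79.6 to 15.9 CPM and the glucose transporter Slc2a3 from 38.2 to 11.4 CPM. The calls of the other members that fell, Hk1, Pgk1 and Slc16a3 (chosen after their values were seen), ended without MLL-ENL dYEATS replicate 1 (adjusted p = 0.413, 0.526 and 0.274) or 2 (0.486, 0.421 and 0.293). Pgk1 was also not called with a minimum of 5 CPM (adjusted p = 0.0553) or with limma on log2 FPKM (0.0591, 0.0605 and 0.12), nor Hk1 in the FPKM fits with a pseudocount of 0.1 (0.0522) and without a filter (0.088). Of 24 ATF4 stress-response genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.504), and Phgdh, the first enzyme of serine synthesis, fell from 198 ± 34.4 to 33.7 ± 0.177 CPM. Aldh1l2 and Ddit4 rose. Aldh1l2 was not called with limma on log2 FPKM (adjusted p = 0.136, 0.156 and 0.199), nor was Ddit4 (0.0762, 0.0757 and 0.12), which also lost its call without MLL-ENL dYEATS replicate 1 or 2 (0.445 and 0.276) and with library quality weights (0.0888). Vldlr, the other member that fell, had no counts in the MLL-ENL dYEATS libraries and was at least 47.1-fold lower.

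Of 27 p53 target genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00902, and adjusted p = 0.656 with an estimated correlation). The adenylate kinase gene Ak1 rose from 1.17 to 7.55 CPM and the kinase gene Plk3 from 4.47 to 12.4 CPM, whereas Phlda3, with 3 counts in the MLL-ENL dYEATS libraries, had a ratio of 34.5 (11.5 to 170). The cell-cycle inhibitor Cdkn1a, chosen after its values were seen, rose from 43.4 ± 2.03 to 78.1 ± 0.585 CPM, a call that ended without MLL-ENL dYEATS replicate 1 or 2 (adjusted p = 0.0674 and 0.0758). Of 40 G1/S genes 3 rose and 1 fell (0 and 0 adjusted over the list alone; adjusted p = 0.377). Rrm2, a subunit of ribonucleotide reductase, rose from 213 to 404 CPM, and the call of Ccne2 ended in 9 alternatives (adjusted p from 0.0512 with a robust fit to 0.375 without MLL-ENL dYEATS replicate 2). Of 40 G2/M genes 1 rose, Bub1, and 0 fell (0 and 0 adjusted over the list alone; adjusted p = 0.0381, and adjusted p = 0.8 with an estimated correlation). The calls of this list (adjusted p = 0.128 and 0.128) and of Bub1 (0.291 and 0.363) ended without MLL-ENL dYEATS replicate 1 or 2, and that of the list with a replicate block (0.0943). Of 24 pro-apoptotic genes 1 rose and 1 fell (1 and 0 adjusted over the list alone; adjusted p = 0.917; median -0.06 and mean -0.02, test up). They were Tnfrsf10b, a death receptor gene not called with limma on log2 FPKM (adjusted p = 0.0697, 0.0845 and 0.174), and Casp1, whose call ended in 8 alternatives (adjusted p from 0.0506 without a filter to 0.408 without MLL-ENL dYEATS replicate 1). Of 15 anti-apoptotic genes 0 rose and 1 fell (0 and 1 adjusted over the list alone; adjusted p = 0.689), the kinase gene Pim1 going from 530 ± 36.3 to 243 ± 3.21 CPM (adjusted p = 0.00269).

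Of 35 ribosome biogenesis and MYC target genes 1 rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.25, 0.00141 without MLL-ENL replicate 1 and 0.0165 with limma on unfiltered log2 FPKM). That gene, Srm, rose from 121 to 189 CPM and was not called without MLL-ENL dYEATS replicate 1 or 2 (adjusted p = 0.324 and 0.26). Of 13 mitochondrially encoded mRNAs 1 rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.399, 2.55e-09 without MLL-ENL replicate 2, 0.027 without MLL-ENL dYEATS replicate 1 and 0.0264 with a replicate block). That gene, mt-Nd3, lay at 26.8 and 7.72 CPM in the MLL-ENL libraries and at 115 and 132 CPM in the MLL-ENL dYEATS libraries. Its log2 fold change was 2.84, 4.0 without MLL-ENL replicate 1 and 2.20 without MLL-ENL replicate 2.

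Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), fell from 121 ± 31.5 to 2.87 ± 0.511 CPM (log2 fold change -5.39 ± 0.27 SE, adjusted p = 0.000402). It was the 1 tested member of the list of X-inactivation and Y-linked genes, and Y-linked Ddx3y had 0 counts in all 4 libraries, each of which allows at most 0.102 to 0.112 CPM at 3 counts. Other genes near the ends of the sex chromosomes, chosen after their values were seen, were not at 0 in all libraries. Gm47283, annotated on chromosome Y (90784738 to 90816464), had 0 counts in both MLL-ENL libraries and 117 ± 3.70 CPM in the MLL-ENL dYEATS libraries, at least 1044-fold higher. Gm21887, annotated on chromosome X (170009659 to 170019281), went from 0 to 89.8 ± 1.22 CPM, at least 801-fold higher, and the split of reads between them is uncertain.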

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

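Removal of the gene-length trend and library quality weights were the alternatives chosen after the data were seen. Genes called with all 4 libraries had the same sign in every alternative that tested them, and the numbers of called genes stayed within 1.5 times of 2235 (2051 to 2905) with other scalings, without a filter, with DESeq2, limma-voom, a robust fit, mitochondrial, ribosomal-protein and haemoglobin genes left out, the trend removed and quality weights. The replicate block gave 3133 genes (1598 at 2-fold) and 11 lists, with G2/M genes lost (0.0943) and mitochondrially encoded mRNAs gained (0.0264). It pairs libraries by number, and the differences within pairs were not related across genes (r = -0.068), so the block has no basis in the data.

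Fewer genes were called with a minimum of 5 CPM (1350, and 694 at 2-fold, with fewer genes tested) and with limma on log2 FPKM: 1135 and 705 with a pseudocount of 1, 1080 and 827 with 0.1, and 674 and 432 without a filter. The cause of the FPKM differences was not tested. glmTreat, which tests against a minimum of 2-fold rather than 0, gave 777. Camera with an estimated correlation called 0 lists (2 at an unadjusted p under 0.05), and fry called 11, of which 7 were also called with the preset correlation. MLL-fusion targets (0.087), G2/M (0.144), adhesion (0.144) and glycolysis genes (0.0862) were not called by fry, and monocyte (0.0372), T-lymphoid (0.0269), G1/S (0.0189) and anti-apoptotic genes (0.0189) were called by it alone.

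Leaving out each library in turn gave 1392 to 9099 called genes, 1323 to 2036 at 2-fold and 10 to 12 lists. The lone library is then assumed to vary like the other group. Without MLL-ENL replicate 1 or 2 that is the close MLL-ENL dYEATS pair, and the counts are the high ones (7465 and 9099). Results that reversed were Kmt2a (-0.28, adjusted p = 1.31e-05) and Myc (-0.23, adjusted p = 2.65e-06) without MLL-ENL replicate 1, against 0.42 and 0.53 without MLL-ENL replicate 2, so no direction is given for either. Without MLL-ENL dYEATS replicate 1 or 2, 16 and 18 named genes lost their calls.

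Of 1783 values of 95 named genes under the alternatives, 1662 kept direction and side of the threshold, 113 lost a call, 6 gained one and 2 reversed. Of 425 values of lists 378 kept both, 37 lost a call and 10 gained one. Among those counted as kept, 4 values of genes and 25 of lists changed sign where no call was made on either side. With limma on filtered log2 FPKM, Lmo2, Eaf1, Mllt6, H2-DMb1, Cd9, Ccne2, Bub1, Tnfrsf10b, Casp1, Nlrp3, Csf1r, Il6ra, Aldh1l2 and Ddit4, and with a pseudocount of 0.1 Rrm2, were not called. Without a filter, Meis1, Rasgrf2, Mmp9, Mpeg1, Gpnmb, Ly6c2, Hdc, Thbs1, Col4a1, Plk3, Oas3, Zbp1, Tnfaip3, Icam1, Slc2a3 and mt-Nd3 were not called either. The same held for Elane, Runx1, Nr4a1, Cdkn1a, Slc16a3 and Cd44, chosen after their values were seen. Calls of primary granule, p53, immediate-early, glycolysis and cholesterol lists held in 14 of 14 alternatives with the preset correlation. Depth limits genes near 3 counts, 0.102 to 0.112 CPM. Simulated data gave back 17.9% of 2-fold changes with the spread of each pair, and 63.9% with an equal spread. Neither share gives the sensitivity on the data.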

Other observations

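Some of the strongest differences lie outside the named genes and lists. Ighm, the immunoglobulin mu heavy chain, chosen after its values were seen, fell from 111 to 0.326 CPM in the MLL-ENL dYEATS libraries (log2 fold change -8.39, adjusted p = 0.000188). The ETS factors Etv4 and Etv5, chosen after their values were seen, rose from 1.48 to 15.5 CPM and from 5.61 to 38.7 CPM. Mid1, a ubiquitin ligase at the edge of the pseudoautosomal region and chosen in the same way, went from 0 to 6.78 CPM, at least 60.5-fold higher.

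Tests chosen only after the result was seen were both tests of MLL-ENL replicate 1, both admixture tests and the test of neighbouring genes, and the interval beside the escape-gene median and the comparison of each admixture median with the called genes were also added after those values were seen. Without its interval, the escape-gene median had met the bound set beforehand against a single X, and with it the question is left open. The neutrophil genes met their bound by sign, but not all by more than 2 times their error (Ltf -0.27, standard error 0.31). That stricter reading leaves neutrophils open, and they are left open here. The tests of X-linked and of neighbouring genes were first run on narrower sets of genes than planned and were rerun on all tested genes, with the same reading.

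MLL-ENL replicate 1 was apart from MLL-ENL replicate 2, and its log2 ratio fell with exonic length (rho = -0.393 across genes, against 0.067 in the MLL-ENL dYEATS pair). RNA integrity or fragment recovery that differs by length may account for part of this. Ribosomal RNA carry-over as the whole cause is argued against: without ribosomal RNA genes the variance of the log2 ratio was still 2.56 times that of the MLL-ENL dYEATS pair. No biological explanation was tested, since the labels give none within a group.

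Xist fell by 5.39 on the log2 scale, and X-linked genes as a whole did not follow. The median of 395 X-linked genes was -0.038 relative to 12819 autosomal genes (95% interval -0.088 to 0.017), which argues against general reactivation of the inactive X. Removal of the gene-length trend left Xist at -5.45. A line with a single X might also lack Xist, and 5 genes that escape X inactivation cannot decide this (median 0.078 relative to other X-linked genes, interval -0.274 to 0.224, permutation p = 0.632 against 10000 random lists). Genotype, line and the animal of origin, untested, stay open.

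Among later neutrophil and monocyte genes 17 were called higher. Admixed neutrophils would bring Ngp, Camp, Ltf and Ly6g as well, and these had a median of -0.68 (SD 0.48, -1.37 to -0.27), against 2.22 for the 11 later neutrophil genes called higher. Camp and Ly6g, low in the MLL-ENL libraries, went from 7.30 to 5.15 and from 1.00 to 0.552 CPM. None of these 4 genes rose, and only Ngp was called lower. They were picked from the same list after its values were seen, so this does not decide on neutrophils. Ngp, Camp and Ltf are made before full maturity, so that cells past that stage were tested by Ly6g alone. Macrophage transcripts Ctsb, Apoe, Ctss, Cd14, Mrc1 and Lyz2 had a median of -0.1 (SD 0.38, -0.5 to 0.51), against 1.04 for the 6 monocyte and macrophage genes called higher, and Ctss was at 2.80 and 2.84 CPM. This does not decide on macrophages, since Lyz2 went from 106 to 152 CPM without being called (adjusted p = 0.0556). Cd68 and Adgre1, outside that set and chosen after their values were seen, were called higher with log2 fold changes of 1.11 and 0.93. Of the whole list 6 members were called higher and 2 lower. The medians of 2.22 and 1.04 are of genes selected for being called. Both test sets come from the same lists and hold no gene called higher, so that lower medians were largely fixed in advance. All 17 stayed called (100%) once the gene-length trend was removed. So did 2207 of all 2235 called genes, and the result is not particular to these 17. A shift in the state of the cells may be involved, with genotype and line not separable.

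Higher ERK-dependent transcription is a candidate explanation of the higher immediate-early genes. It was tested on 7 ERK output genes not looked at before, of which 5 were tested for differences. Their median of 2.5, the value of Dusp4, was at percentile 100 of 10000 lists matched on expression. Dusp4 had 11 and 8 counts in the MLL-ENL libraries and Epha2 had 0 and 0, too few to pass the filter without the MLL-ENL dYEATS libraries. These genes could enter only as increases, so the percentile cannot decide the question. Dusp4 and Ccnd1 rose with log2 fold changes of 2.5 and 3.19, and Epha2 was at least 53.3-fold higher, but Phlda1 (0.04) and Spry2 (-0.11) were not called. Activity of the kinase itself was not measured here.

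Strongly lower genes often lay side by side. Among 543 genes lower by a fitted 4-fold or more there were 74 neighbouring pairs, against a mean of 23.4 in random sets matched on expression (permutation p = 0.0001, the smallest 10000 sets can give). Regional loss or silencing could give this, but 284 genes higher by as much also formed 28 pairs against 6.41, so the test does not single it out. Families of adjacent copies such as Xlr and Stfa are among the pairs.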
